A study of Mus musculus with 8 samples.

How the data were processed

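RNA of mouse jejunum was labelled with Cy3 and hybridised to one-colour Agilent arrays, 4 for DJB and 4 for Sham surgery. Groups and replicate numbers were taken from the sample titles. Each scanner file holds spot intensity values that the authors made with Feature Extraction 10.7.1.1, per the file headers, and the submitters' processing notes name Agilent Feature Extraction 10.7 and limma. The processed signal is a background-corrected intensity on a linear scale, per the file headers. The deposited table of the series holds log2 values, whose scale and normalization are unstated. Set against log2 scanner signals that were quantile normalized here, its columns differed by a median of 0.00271 to 0.00275 with Pearson's r of 0.998 to 0.999 across probes. Its column medians were 6.22, 6.23, 6.22 and 6.22 for DJB replicates 1 to 4 and 6.22, 6.22, 6.22 and 6.21 for Sham replicates 1 to 4. It lists 65478 of the non-control probes, was not centred per gene, and served as an alternative.

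Each array held 176026 non-control spots of 90752 probes, 85274 with 2 spots and 5478 with 1, and 4854 control spots. From each log2 processed signal the array's 75th percentile over non-control spots was subtracted. Spots marked as non-uniform or population outliers, 151 to 310 on DJB and 58 to 102 on Sham arrays, were left out, and spots of a probe were averaged. No array had saturated non-control spots (0 in all). Probes were kept where all their remaining spots were well above background on at least 4 of the 8 arrays, which left 58717. Of these, 5 had under 2 values in a group and 58712 were tested with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Scanner files were read with the R package data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision. No 2 arrays were identical, and the smallest median absolute difference between a pair was 0.11 on the log2 scale.

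For a probe not well above background on any array of a group, the fold is a bound, the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Array measures were compared with exact permutation tests over 70 splits, and the number of outlier spots was added to them after seeing the data. Overlaps were sought as shared stretches of 25 bases, leaving out stretches found in over 20 probes.

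The design fixed before the data were examined counted protein-coding genes and noncoding RNAs apart, took the brightest probe of a gene, and tested gene lists and cell type markers. None of this could be followed, since the files pair no probe with a gene, and probes were tested instead. The fixed rule for named items took the largest rises and falls among changed probes well above background on all 8 arrays with no overlap between groups, and those with the smallest adjusted p among probes detected in all arrays of 1 group and none of the other. After the data were examined, this was restricted to the first of each in each direction, because unnamed probes are limited to 2 that rose and 2 that fell.

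The fit was tested on simulated arrays for the DJB and Sham comparison, with 200 of 58675 probes changed. It recovered 73.0% of them at 2-fold, with 6 unchanged probes called, and 96.5% at 4-fold, with 17 unchanged probes called. With nothing changed it called 0. The simulation drew noise independently for each probe and array, with no difference between slides. It changed far fewer probes than the 31.3% called in the data. Its recovery therefore does not give the power of the real comparison, and its false calls say nothing of slide effects. Alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50, other filters and thresholds, outlier spots kept, the deposited values, the replicate number as a block, other eBayes options, array weights and leaving out each array. Removal of the GC trend, scaling on 9 spike-in probes, averaging of overlapping probes and restricted probe sets were added after seeing the data.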

Results

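The arrays measured RNA from the jejunum of male C57BL/6 mice, an inbred strain, 2 weeks after surgery, at 21 weeks of age. A high-fat diet began at the age of 6 weeks and lasted 12 weeks before surgery. It left 32 of 60 mice diabetic, and these were assigned at random to DJB, a bariatric operation (18 mice), or to a sham operation (14 mice). Each group was measured on 4 one-colour arrays, which held 90752 non-control probes of 60 bases. The labels of tissue and title give jejunum, whereas the extraction protocol in the labels names the duodenum, so the segment rests on the former. The labels do not say that each array came from a separate mouse, so p-values measure the spread between these samples.

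The files pair no probe with a gene name. Each probe carries only a number, its sequence and no position, and the label does not separate coding from noncoding transcripts. The comparison that the design implies, which transcripts of the jejunum differ between DJB and sham surgery, was therefore made probe by probe, and at most 2 probes are named in each direction.

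The probe MOUSELNCRNA_36147, with the sequence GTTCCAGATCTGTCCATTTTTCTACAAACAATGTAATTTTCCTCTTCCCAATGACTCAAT, rose the most among the probes well above background on all 8 arrays. Its log2 signal relative to the array's 75th percentile was 4.87 ± 2.30 (SD, n = 4) in DJB and -2.12 ± 0.49 (SD, n = 4) in Sham, a log2 fold change of 6.99 (SE 0.98) or 128-fold, with a limma adjusted p of 0.00218. The DJB arrays themselves differed widely, from 1.47 in replicate 4 to 6.39 in replicate 1, and without replicate 4 the log2 fold change was 8.13. MOUSELNCRNA_8636, with the sequence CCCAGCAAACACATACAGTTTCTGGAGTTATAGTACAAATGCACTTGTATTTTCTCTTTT, fell the most. Its level was -3.09 ± 0.81 (SD, n = 4) in DJB and 0.98 ± 1.27 (SD, n = 4) in Sham, a log2 fold change of -4.07 (SE 0.63; limma adjusted p = 0.00308), or 16.8-fold lower. It was -3.09 with normexp background correction and -4.70 with array quality weights. These probes were taken from 14753 changed probes that were well above background on all 8 arrays and whose groups did not overlap, of which 9014 were higher and 5739 lower in DJB.

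MOUSELNCRNA_956, with the sequence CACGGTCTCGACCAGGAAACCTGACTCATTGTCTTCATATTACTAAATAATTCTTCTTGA, was well above background on all 4 DJB arrays and on 0 Sham arrays. It was at least 35.7-fold higher in DJB, with a level of 0.11 ± 0.45 (SD, n = 4) there. The limma adjusted p of 9.55e-05 belongs to the fitted log2 fold change of 7.11 (SE 0.27), not to the bound. That fit used Sham signals that were not well above background. The bound holds for the scaling used, and with normexp background correction the log2 fold change was 3.28. MOUSELNCRNA_53027, with the sequence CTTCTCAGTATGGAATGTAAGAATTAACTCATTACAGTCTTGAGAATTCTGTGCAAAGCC, was well above background on all 4 Sham arrays and on 0 DJB arrays. It was at least 1.02-fold lower in DJB, a bound set by its Sham level of -4.55 ± 0.07 (SD, n = 4), which lay close to the lowest signals well above background. The limma adjusted p of 2.37e-04 belongs to the fitted log2 fold change of -2.23 (SE 0.10). That fit used DJB signals not well above background, so the p does not apply to the bound.

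**Figure D1:**
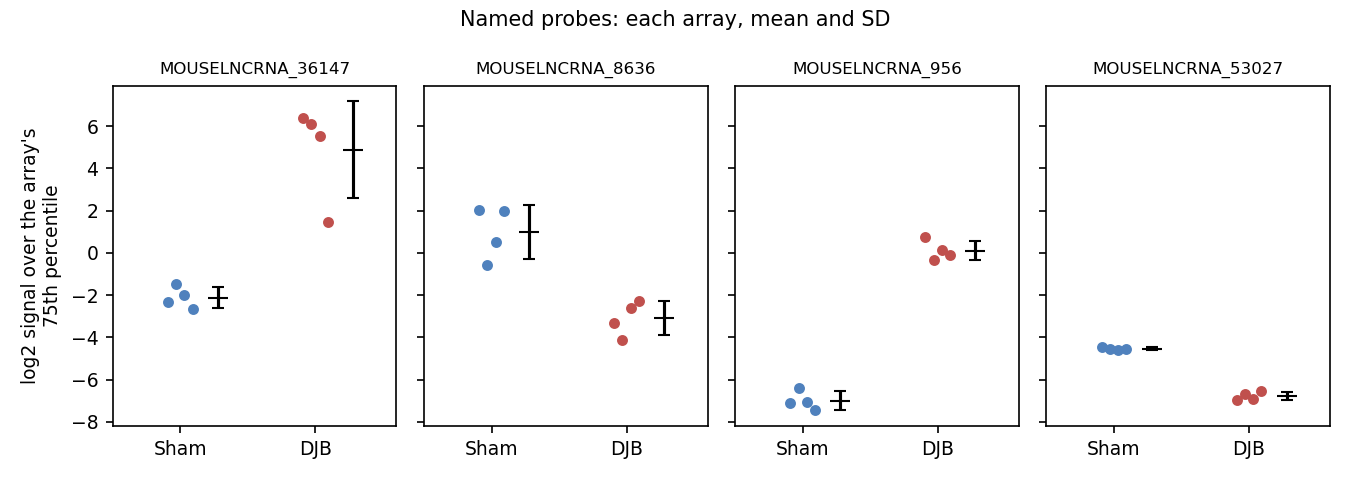
Log2 signal over the array's 75th percentile for the 4 named probes, with each point 1 array and the bar the mean and SD of 4. Values of MOUSELNCRNA_36147 run from 1.47 to 6.39 in DJB, and the Sham values of MOUSELNCRNA_956 and DJB values of MOUSELNCRNA_53027 were not well above background.

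Of 58712 probes tested, 18403 (31.3%) changed at a limma adjusted p under 0.05, with 11003 higher and 7400 lower in DJB. Leaving out any 1 array gave 7989 to 10379 higher and 4562 to 7166 lower. Most changes were small. The median absolute log2 fold change of changed probes was 0.50, or 1.41-fold, against a median SE of 0.11 over all tested probes. At least 2-fold changes were found for 1739 probes, 906 higher and 833 lower, and at least 4-fold changes for 254, 166 higher and 88 lower. The groups did not overlap for 34.3% of tested probes, where chance gives 2.86%. The higher probes made up 59.8% of those changed, but 48.2% after quantile normalization, 36.2% with arrays centred on their median, 49.0% in the deposited values and 37.7% with arrays scaled on spike-in probes. It was 67.6% with normexp background correction and 75.1% with no filter on dim probes. Centring each array on the median of all its non-control spots, dim ones included, moved the median log2 fold change of the tested probes from 0.04 to -0.07. Which direction held more probes therefore depended on the scaling. All DJB arrays were on 1 slide and all Sham arrays on the other, so slide and group cannot be told apart.

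The lowest signal well above background was higher on the DJB arrays, from -4.67 to -4.37 on the log2 scale, than on the Sham arrays, from -5.31 to -4.90, which bears on what was detected in each group. A set of 61 probes was well above background on all DJB arrays and on no Sham array. All 61 passed the test, and 46 of them were at least 2-fold higher by the bound, not by the fitted fold change. The opposite set held 546 probes, of which 333 passed the test and 30 were at least 2-fold lower by the bound. The higher limit on the DJB arrays makes the bounds of this second set smaller. Both sets were chosen by detection in the same signals, so passing the test is no separate support. The other splits of the arrays into 4 and 4 gave at most 121 such probes in both directions together, against 607 in the real one. Every other split mixes both groups, and so both detection limits, in each arm, so few such probes were likely there. The comparison therefore does not decide about chance or about the slides. The share of probes well above background was 62.6% ± 1.45 (SD, n = 4) in DJB and 65.3% ± 1.47 (SD, n = 4) in Sham, a difference of -2.74 percentage points (exact permutation test, two-sided, p = 0.0571, adjusted p = 0.103 over 9 array measures).

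The 75th percentile of the raw intensity was 524 ± 22.7 (SD, n = 4) in DJB and 583 ± 21.9 (SD, n = 4) in Sham (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0643). Negative control spots lay at -6.81 ± 0.14 (SD, n = 4) relative to it in DJB and at -7.27 ± 0.19 (SD, n = 4) in Sham (exact permutation p = 0.0286, adjusted p = 0.0643). That p is the smallest that 4 arrays against 4 can give, and none of the 9 array measures passed the adjustment. Passing would have needed most of the 9 to reach that p, so not passing does not show that the slides were alike. The 75th percentile, the negative controls, the outlier spots and the slope on GC content all reached it. Spots marked as outliers numbered 151, 310, 188 and 234 on the DJB arrays and 86, 102, 73 and 58 on the Sham arrays, with no overlap (exact permutation p = 0.0286, adjusted p = 0.0643). The E1A spike-in probes, RNA added in known amounts, differed between the groups by a median of 0.06 on the log2 scale over 9 probes, from -0.01 to 0.40.

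Sham arrays resembled each other more than they resembled DJB arrays, whereas the lowest correlation within DJB did not exceed the highest between the groups. Pearson correlations across probes, which are not independent replicates, were 0.987 to 0.994 within DJB, 0.994 to 0.997 within Sham and 0.976 to 0.988 between the groups. The first principal component held 57.0% of the variance and parted the groups, with scores from 31.9 to 88.2 in DJB and from -60.0 to -46.3 in Sham. The second held 15.1% and spread mainly the DJB arrays, from -54.2 in replicate 3 to 42.3 in replicate 1. The median SD of a probe was 0.17 between DJB arrays, 0.12 between Sham arrays and 0.07 between the 2 spots of a probe on 1 array.

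**Figure D2:**
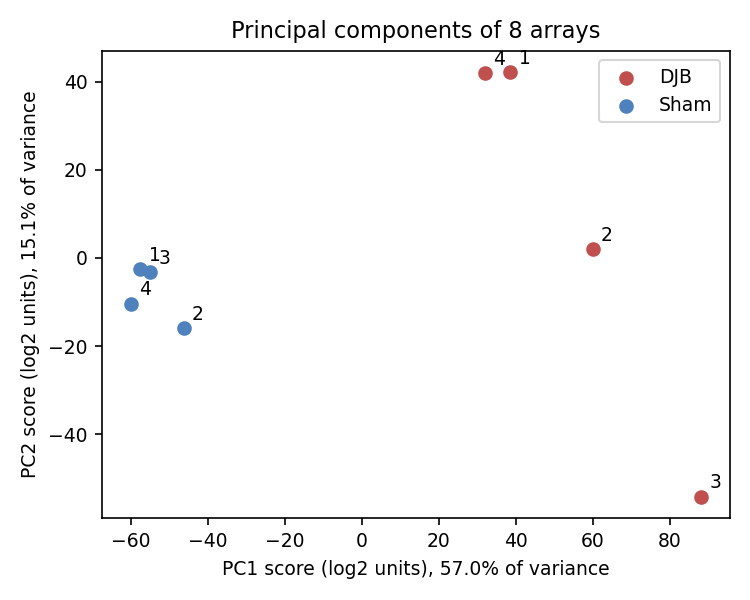
Scores of the 8 arrays on the first and second principal component of log2 signals, with the replicate number beside each point. On the first component the DJB arrays run from 31.9 to 88.2 and the Sham arrays from -60.0 to -46.3.

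Probes that share sequence on the same strand gave similar fold changes. Over 2440 pairs that share at least 25 bases and overlap no other probe, log2 fold changes correlated across pairs with Pearson's r = 0.913 and Spearman's rho = 0.891 (permutation p = 1e-04 for r, the smallest that 10000 draws can give). Both probes changed in 526 pairs, and in 522 of these the direction was shared, or 99.2%, where chance gives 50.02%. Probes that share sequence may bind the same RNA, so such agreement was likely beforehand. A difference between the slides could be shared by both probes too, so the agreement is no separate support for the changes. Of 3106 pairs that overlap on opposite strands, 169 overlap no other probe. Over these 169, Pearson's r was 0.107 and Spearman's rho 0.194 (permutation p = 0.162 for r).

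**Figure D3:**
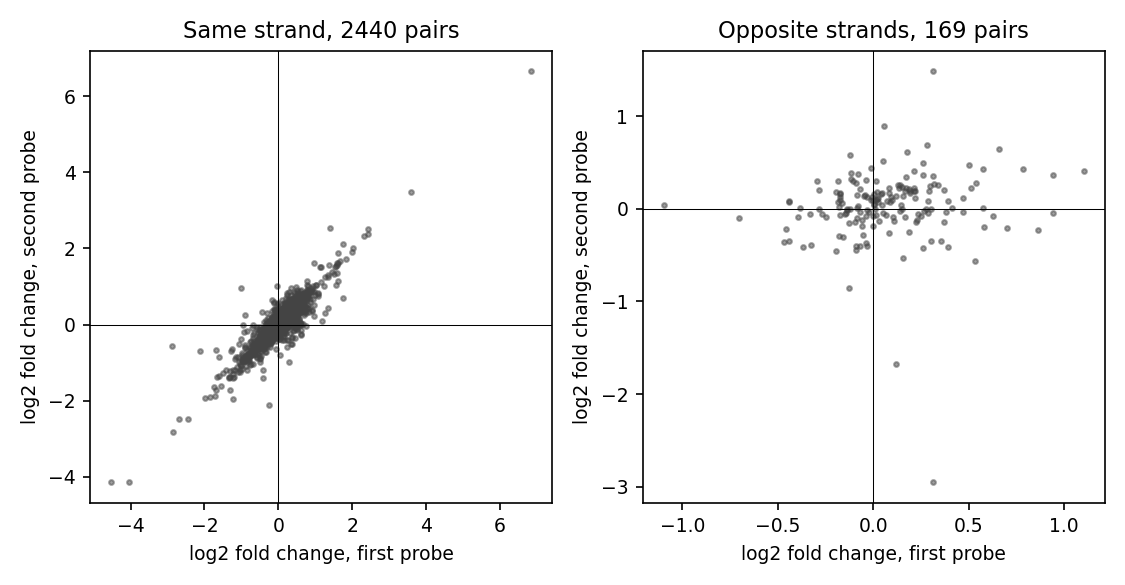
Log2 fold change, DJB over Sham, of 1 probe against that of the overlapping probe. Shown are 2440 pairs on the same strand and 169 on opposite strands that overlap no other probe. Each point is a pair, and Pearson's r is 0.913 on the left and 0.107 on the right.

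The share of probes higher in DJB was larger at higher GC content of the probe. Among 14238 probes of at most 35% GC, 11.1% were higher and 16.95% lower in DJB, whereas among 2334 probes over 55% GC, 33.8% were higher and 3.64% lower. Per array, the slope of the log2 signal on GC content was 0.0652 ± 0.00942 (SD, n = 4) per 10 points in DJB and -0.0652 ± 0.0167 (SD, n = 4) in Sham, relative to the mean of all 8 arrays (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0643 over 9 array measures, which did not pass). Over 10 classes of signal from dim to bright, the slope of the fold change was 0.29 per 10 points in the dimmest class and -0.01 in the brightest.

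**Figure D4:**
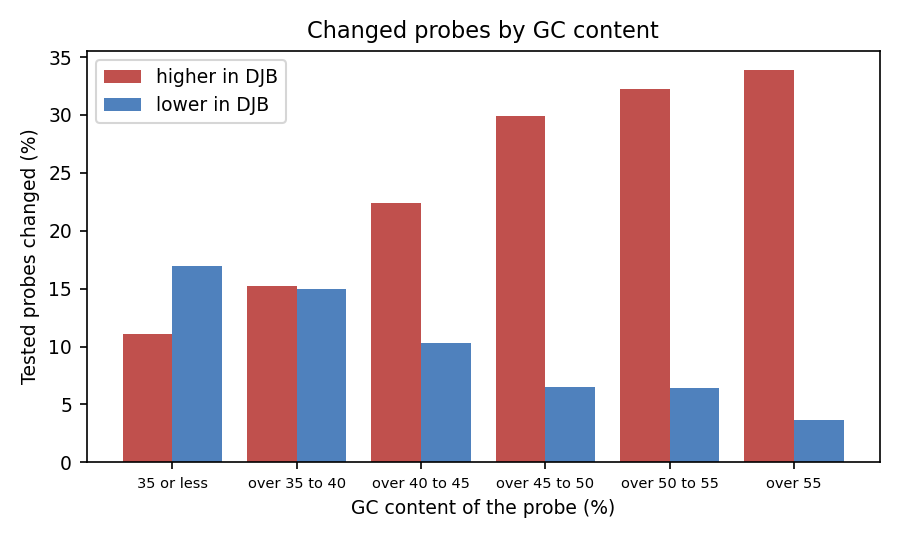
Percent of tested probes higher and lower in DJB (limma adjusted p under 0.05) in classes of probe GC content. The share of higher probes is 11.1% in the lowest class and 33.8% in the highest.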

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

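The tests on spike-in and other control probes, slides, the GC correction and the brighter probes were chosen after the result was seen, whereas centring on the median was chosen before the data were examined and only its reading as a test was written afterwards. Control probes enter no count of changed probes, and 3 of the 26 well above background on all arrays were higher on every DJB array than on any Sham array. ERCC-00062_278 differed by 0.63 on the log2 scale, ETG05_66023 by 0.54 and the spike-in (+)E1A_r60_3 by 0.40. Each had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.248 over the 26. Passing the adjustment would have needed most of the 26 to reach that p. By Dixon's test at the 95% level no array passed as apart in the 30 sets of 4 values examined, although MOUSELNCRNA_36147 was 1.47 in DJB replicate 4 beside 5.51 to 6.39 on the other DJB arrays.

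The first pattern is the number of changed probes, 18403. Among the 35 splits of the arrays into 4 and 4, only 1, the real one, gave as many, and the highest other gave 1. Every other split mixes both groups in each arm, which turns the group difference into spread, so few calls were likely there. The real split is also the split by slide, and 1 of 35 is the smallest share possible. The rank therefore does not decide about chance. Chance differences between mice are not excluded, since the labels do not say that arrays are separate mice. The spike-in probes differed by a median absolute 0.0594 beside 0.50 for changed probes, but this decides nothing about a shift of the whole signal between slides, which the scaling of each array takes out beforehand. A difference between slides or their handling that affects some probes more than others cannot be told apart from the surgery, because 0 slides hold both groups, and the surgery itself stays open.

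The second pattern is that more changed probes were higher than lower in DJB, 59.8%. With the GC trend removed the share was 59.6% where each array's median was left in place, and 51.3% where it was removed too. The first holds the balance of directions and the second evens it, so neither decides and the trend stays open. The scaling may account for the excess, since centring on the median gave 36.2%. Background at low signal stays open, since probes brighter than the median gave 50.4% but the brightest of 10 classes of signal gave 59.8% and normexp background correction 67.6%. No biological explanation of the excess was tested.

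The third pattern is the rise of fold change with GC content, 0.13 per 10 points (log2). Within 10 classes of signal the median slope was 0.15, above the limit of 0.0652 set before the test, but the classes ran from 0.29 in the dimmest to -0.01 in the brightest and 3 of the 10 stayed below that limit, so the median alone was a poor test and a part of signal level stays open. Within 3119 groups of overlapping probes the slope was 0.0442 (95% bootstrap interval 0.0252 to 0.0647). That interval lies above 0 and below the slope over all probes. Its upper bound is barely under 0.0652, the limit set before the test. GC content within these groups deviated by a median of only 1.11 points, so a slope per 10 points is extrapolated. The limit came from all tested probes, whereas the slope between the means of these groups was 0.114. The test therefore does not decide, and hybridization of single probes stays open. Labelling or handling of whole transcripts and the surgery were not tested and stay open.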

How the results depend on the processing

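Spike-in scaling, GC correction, overlapping probes averaged, the deposited table's probes and the brighter probes were added after seeing the data, as was every alternative for the GC slope. The direction and threshold of the 4 named probes held in all 85 alternative values that could be computed for them, but the sizes moved. These probes were picked from the same arrays for their large or clear changes, so this is no independent support. The log2 fold change ran from 6.45 to 8.13 for MOUSELNCRNA_36147, from -4.70 to -3.09 for MOUSELNCRNA_8636, from 3.28 to 7.31 for MOUSELNCRNA_956 and from -2.54 to -0.34 for MOUSELNCRNA_53027, with the values nearest 0 under normexp. Counts of changed, higher and lower probes moved by over 1.5 times as follows. With no filter on dim probes 30456 changed and 22866 were higher. Among probes brighter than the median 7874 changed, 3968 higher and 3906 lower, where fewer were tested. At adjusted p under 0.05 and at least 2-fold there were 1739, 906 and 833, at unadjusted p under 0.05 and at least 2-fold 1870, 953 and 917, and at adjusted p under 0.01 there were 7850, 5341 and 2509. Centring on the median gave 7137 higher and 12558 lower, the deposited values 6378 higher over fewer probes, and spike-in scaling 5880 higher. Without any 1 array, 12559 to 17527 changed, 7989 to 10379 were higher and 4562 to 7166 lower, with 4562 lower without Sham replicate 1 and 4594 without Sham replicate 4. With the replicate number as a block, 15670 changed, 9385 higher and 6285 lower. Same-numbered arrays deviated with correlations of 0.141, 0.106, -0.0503 and 0.108, not all over 0.1, so the numbers were not taken as pairs. However, 3 of 4 DJB arrays correlated best with their own number, so a shared effect of the number stays open. The position on the slide has the same number. The share well above background differed by -3.30 percentage points without DJB replicate 1 (exact permutation p = 0.0286, unadjusted and the smallest possible). Leaving out any other array gave -3.12 to -2.04, with exact permutation p from 0.0571 to 0.114. With all arrays it was -2.74 (exact permutation p = 0.0571). For the remaining moves the cause was not tested. The GC slope stayed above 0 in the alternatives run for it, but fell from 0.13 to 0.0533 among probes brighter than the median, 0.0806 with normexp and 0.0843 with no filter. Its exact p stayed at the smallest possible value, which says nothing of stability. The slide as a block, a mean over a gene's probes, camera and fry were not run, since no slide holds both groups and no probe has a gene. Signal over background limits the dimmest probes.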

Other observations

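The tests in this part were chosen after related results had been seen. Many probes of the array share a stretch of sequence. The stretch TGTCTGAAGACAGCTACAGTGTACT is in 99 tested probes, whose median log2 fold change was 0.08, with 0 higher and 1 lower in DJB; the sign of that median turned under quantile normalization (-0.03) and centring on the median (-0.03). The stretch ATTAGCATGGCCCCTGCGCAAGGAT is in 85 tested probes, of which 84 fell, with a median log2 fold change of -0.38 and a range of -0.47 to -0.26. Its median was -0.39 under quantile normalization and under normexp, and -0.49 with arrays centred on the median. The files do not say which transcripts these are.

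Whether either family moved more than other probes could not be decided. Among single probes of like GC content and signal, the first family's median lay at percentile 56.3 and the second's at 7.29, but single probes vary more than a median does. Among sets of as many unrelated probes the second lay at percentile 0, but probes that share sequence may bind the same RNA and are not independent. The hypothesis that probes on opposite strands change together was tested only on the 169 pairs that overlap no other probe. Their Pearson's r of 0.107 lay below the 0.125 that 95% of random pairings stay under. Spearman's rho, 0.194, was larger and was not tested against random pairings. With so few such pairs the hypothesis stays open.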
